A study of Drosophila melanogaster with 2 samples.

How the data were processed

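Bowl, a zinc-finger transcription factor of the odd-skipped family, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos aged 0 to 24 h. Per the labels, the embryos carried a bowl-eGFP fusion transgene, chromatin was sheared by sonication with a stated size range of 200 to 800 (no unit is given), and the precipitation used an antibody against GFP. The 2 samples are biological replicates of 1 group, Bowl-eGFP embryo, and no second group was profiled, so the comparisons made here are between replicates, and between peaks and the candidate regions that did not become peaks.

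The deposited files are peak lists on the dm6 assembly, per the labels. For each replicate, and for both replicates pooled, the authors deposited a ranked list of candidate regions and a thresholded list. The pooled data have 2 thresholded lists: a larger one, called the pooled list here, and a smaller one marked as conservative by the authors. Notes deposited with each sample trace the lists to alignments, a control and, for thresholded lists only, 1 further file whose content was not analysed here. The aligner, the peak caller and their versions are not given in the sources used here. The control was not analysed here.

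The peak signal of each region is a score that the authors' peak caller gave it, taken as deposited. It has no stated scale and was used only to describe, rank and filter peaks within a list. The second deposited score is the −log10 of the global irreproducible discovery rate (IDR), a measure of how well ranks repeat between 2 peak sets, and a value of 2 stands for an IDR of 0.01. Tested on the files, every listed peak had a −log10 IDR of at least 2 in the ranked list of its kind, and each thresholded list lacked some candidates past that value. The conservative list was cut from the ranked list that compares the 2 replicates, and the pooled list from a separate ranked list of the pooled data. In the ranked list that compares the 2 replicates, 2 unnamed columns hold the signal of each replicate, and they were used without assigning them to replicates. Read depth is unknown, since the lists hold no read counts. Intervals on shares are 95% Wilson intervals and cover counting error over peaks only. Peaks lie in clusters and are not independent replicates, so p-values over peaks describe these lists and not the spread between embryo collections.

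Positions were annotated with Ensembl release 115 gene models for the BDGP6.54 annotation and with the RefSeq Release 6 sequence, which is the dm6 assembly. A summit was placed in a promoter if it lay within 500 bp of a transcription start site (TSS) of a protein-coding gene, and otherwise in coding sequence (CDS), 5' UTR, 3' UTR, intron or intergenic sequence, in that order. The background was the set of pooled candidates with a −log10 IDR under 2, called failing candidates. Shares by feature, by chromosome arm and near small RNA genes (tRNA, snRNA, snoRNA or rRNA genes within 500 bp) were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over classes or arms. Sequence words were counted on both strands within 50 bp of the summit and compared with failing candidates matched on feature class and GC decile, using 10000 matched draws, whose smallest two-sided p is 0.0002. These were binomial draws at the word's share in the candidates of each class and decile, and their p is called a permutation p. Against flanks 1 kb away, draws used the mean share of the flank windows, without matching or pairing each peak with its own flanks. That binomial p ignores the counting error of the flank share, so it is too small. The panel held 19 words for known factors, adjusted over the panel. All 8-base words were ranked by the same enrichment with 10 matched candidates per peak. The words were written from memory and are short forms of each factor's preference.

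Peaks were assigned to the nearest TSS of a protein-coding gene. For each of 18 gene lists, the number of genes with a peak was compared with 100000 random lists matched on the number of candidate regions per gene (in deciles), with a two-sided permutation p, whose smallest value is 2e-05, adjusted over the 16 lists with at least 5 genes in the background of 12783 genes. Listed names that were absent from the annotation were matched through RefSeq synonyms, 3 ambiguous ones by hand, and 4 names stayed unmatched. Replicate lists were compared by overlaps of at least 1 bp, with chance from 100 random draws of as many candidates. The rank agreement of replicate signals is Spearman's rho across peaks, and Pearson's r on log2(signal + 1), with no p-value. The Spearman values of 2 of its alternatives (all candidates, and the conservative list) are not reported here and not counted among the alternatives, because of a restriction on wording and not because of their values, which lay outside the interval of the main value.

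The genes named were bowl, odd, sob and drm, the 12 genes with the most peaks (ties by signal), the genes assigned to the 10 peaks of highest signal, and in each tested list the 3 members with the strongest peak, plus the next 2 for the Notch, Wnt and gut lists. Lists, words, tests, this rule and most alternatives were fixed before the data were examined. Alternatives covered promoter width, window width, background, assignment of genes, overlap criterion, a stricter list and each replicate's own list. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

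The tests were tested on simulated data, with 2198 peaks drawn from failing candidates. A planted log2 promoter ratio of 1.22 came back as 1.18, and with nothing planted 1 of 120 class tests passed an adjusted p of 0.05. A word planted in 2.55% of peaks raised its share by 2.55 percentage points, and with nothing planted 2 of 380 panel tests passed. A list with 27 planted genes was recovered with 30 genes and an adjusted p of 3.2e-04 by the permutation test, and with nothing planted 0 of 320 list tests passed. The runs with nothing planted drew peaks evenly from failing candidates. They do not show how the tests behave for peaks that favour promoters or lie in clusters, as the real ones do.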

Results

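Binding of Bowl-eGFP was mapped in 2 biological replicates of whole embryos aged 0 to 24 h. The pooled list held 2198 peaks, 1.66% of 132019 candidates, and covered 637637 bp, with a median peak width of 310 bp. The conservative list held 1557 peaks, of which 1421 were identical to peaks of the pooled list. Signal in the pooled list ran from 2.15 to 1467, with a median of 82.6, against a median of 18.4 in failing candidates.

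The strongest Bowl-eGFP peaks lay mostly in promoters, 8 of the first 10, of genes with varied functions. The peak of highest signal, 1467, was in an intron of CG11050 (2L, 6612404 to 6612902), 1010 bp from a TSS. Next came promoter peaks of Ugalt, a UDP-galactose transporter gene, with a signal of 887 (X, 2703746 to 2704012), CG14100 with 817 (3L, 19590494 to 19590729), PNPase, which encodes the mitochondrial polynucleotide phosphorylase, with 725 (3R, 31404537 to 31404782), and mRpL41, a mitochondrial ribosomal protein gene, with 710 (2R, 15217627 to 15217884). Dll, the homeobox gene of distal appendages, had a promoter peak with a signal of 697, 80 bp from its TSS (2R, 24814575 to 24814866). The Polycomb-group gene ph-p had a peak of signal 696 in an intron (X, 2137228 to 2137479), 501 bp from a TSS and so 1 bp outside the promoter class. CG7601 (signal 686), CenG1A (663) and CG18549 (629) completed the 10 strongest peaks, all 3 in promoters and between 103 and 118 bp from a TSS.

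All 4 genes of the odd-skipped family carried peaks. The bowl gene itself (2L, 3771700 to 3784121) had 7 peaks: 3 in promoters, 3 in introns and 1 intergenic. Its strongest, with a signal of 431 and rank 35 of 2198, lay 228 bp from the TSS (3771367 to 3771592), and the next, in an intron (3776567 to 3776876), had a signal of 119. The gut gene drm had 3 peaks, with signals of 223, 190 and 98.7, the first 174 bp from the TSS (2L, 3539513 to 3539648). Single promoter peaks lay at odd, a pair-rule gene, with a signal of 86.4 (2L, 3606620 to 3606929), and at sob, with 77.1 (2L, 3580797 to 3581106). With 4 genes the family was too small for the planned test, and random lists matched to it gave a mean of 1.21 genes with a peak. The embryos carried a bowl transgene, and a peak list cannot tell its copy of bowl from the chromosomal one.

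**Figure D1:**
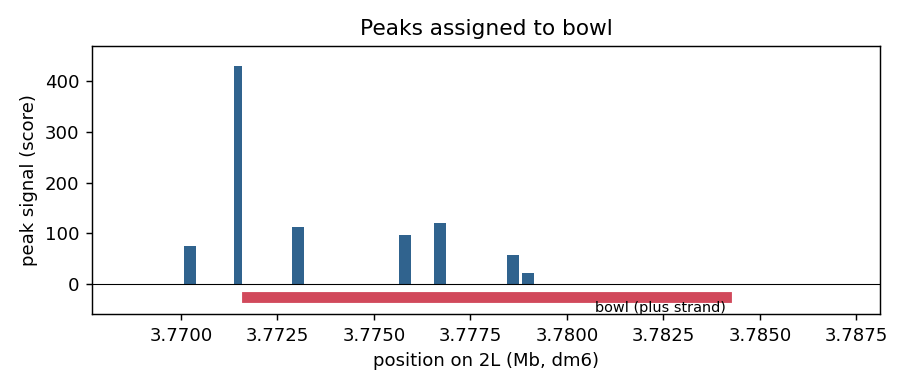
Peak signal (score, vertical axis) of the 7 peaks assigned to bowl against their position on 2L in Mb (dm6), with the gene body drawn below the axis. The strongest peak, with a signal of 431, stands 228 bp from the TSS, and the other 6 lie between 21.2 and 119.

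Peaks per gene were uneven. The 2198 peaks were assigned to 1641 genes, of which 1282 had a single peak and 24 had 5 or more. CHES-1-like, a forkhead-domain gene, had the most, with 10 peaks, 8 of them in introns (strongest signal 374; X, 7706884 to 7707083). It was followed by shn, a zinc-finger gene of Dpp signalling, with 9 peaks (strongest signal 241), and ftz-f1, a nuclear receptor gene of segmentation and moulting, with 8 (88.4). The transcriptional regulator sbb had 7 peaks (strongest signal 189), as did bowl and CG43245 (164), and all 7 at CG43245 were intergenic. Tlk, a chromatin kinase gene, had 6 peaks with a strongest signal of 522. CG1888 (strongest signal 489), chinmo (282), the nuclear receptor coactivator gene tai (168), the ubiquitin ligase adaptor gene rdx (168) and bun (114) also had 6 each. The strongest chinmo peak was intergenic, 18449 bp from the TSS.

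Whether peaks favoured certain gene features was tested against failing candidates. Promoters held 1077 of 2198 summits, 49.0% (95% interval 46.9 to 51.1), against 14.4% of failing candidates, a 3.4-fold excess (log2 ratio 1.77, adjusted p = 2.1e-314, Fisher's exact test). Coding sequence held 1.91% of summits (1.42 to 2.57) against 22.6% of candidates (log2 ratio -3.57, adjusted exact p = 2.2e-176). Intergenic summits made up 13.6% against 22.3% (log2 ratio -0.71, adjusted exact p = 6.2e-24), and 3' UTR summits 1.14% against 3.28% (log2 ratio -1.53, adjusted p = 2.8e-10). Introns held 33.5% against 36.6% (log2 ratio -0.13, adjusted exact p = 0.0029), and with promoters narrowed to 200 bp the intron ratio changed sign to 0.057 (adjusted p = 0.14). The 5' UTR share, 0.819% against 0.794%, did not differ detectably (adjusted exact p = 0.81). Promoter summits lay upstream of the TSS in 762 of 1077 cases, 70.8% (68.0 to 73.4), with a median position 89 bp upstream, whereas 39.4% of 18544 promoter candidates did (p = 8.7e-91, Fisher's exact test). The promoter share was 44.9% (40.8 to 49.1) in the 25% of peaks with the lowest signal and 54.4% (50.2 to 58.5) in the 25% with the highest.

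**Figure D2:**
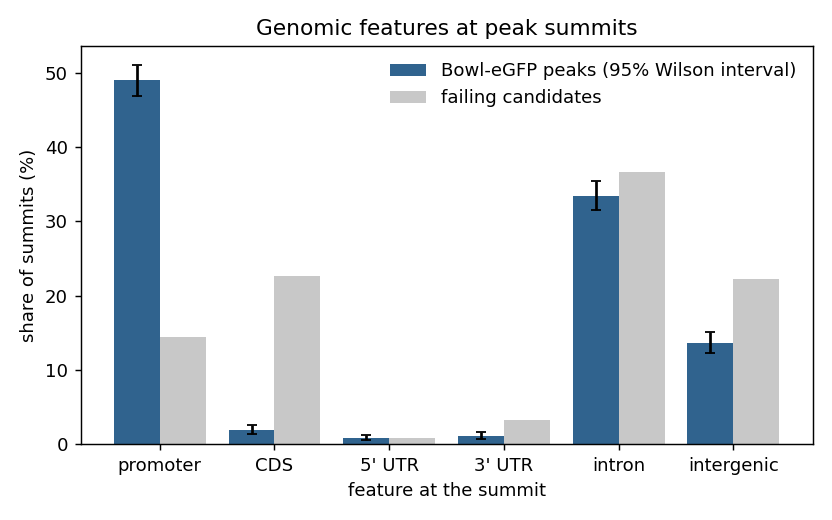
Share of summits (%, vertical axis) in each feature class for the 2198 Bowl-eGFP peaks (bars with 95% Wilson intervals) and for the 128710 failing candidates on the chromosome arms. Promoters held 49.0% of peak summits against 14.4% of candidates, and coding sequence 1.91% against 22.6%.

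None of the chromosome arms passed the adjusted threshold in the pooled list. The arm 3R held 22.2% of peaks against 24.4% of candidates (adjusted exact p = 0.064), 2L 19.3% against 17.7% and 2R 20.2% against 18.5% (adjusted p = 0.097 each), 3L 20.2% against 19.9% (adjusted p = 0.71), X 17.8% against 18.5% (adjusted p = 0.50) and chromosome 4 0.364% against 0.234% (adjusted p = 0.25). Other scaffolds, meaning every sequence outside the arms, chromosome 4 and Y, held 0 peaks. That allows a share of up to 0.174%, against 0.788% of candidates (adjusted exact p = 4.3e-07). Y held 0 peaks against 0.113% of candidates (adjusted exact p = 0.25). Among peaks at or above the median signal 3R passed, with 20.9% against 24.4% of candidates, and so did 2L, with 20.7% against 17.7% (adjusted exact p = 0.023 each). In replicate 1's list 3R passed as well (21.5% against 24.7%, adjusted exact p = 0.021). Of the 89 candidates that passed the IDR threshold and were missing from the pooled list, 51 lay on 3R, which lowers its share. Some of the missing candidates lay on other scaffolds. With the missing candidates added back, these scaffolds held 0.0875% of peaks against 0.788% of candidates (adjusted exact p = 4.5e-05). The deficit on other scaffolds did not pass in the list of either replicate.

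Cytoplasmic ribosomal protein genes were the tested list that passed the adjusted threshold against matched random lists in the pooled list. Of 90 such genes, 44 had a peak against 7.81 expected, a 5.63-fold excess (adjusted p = 3.2e-04, the smallest these permutations can give). The strongest were at RpL7 (signal 192, 33 bp from the TSS; 2L, 10200882 to 10201191), RpL32 (185; 3R, 30046254 to 30046352) and RpS27 (177; 3R, 25247452 to 25247557). Promoters held 43 of the 47 peaks assigned to these genes. The excess passed the threshold in the list of either replicate.

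None of the signalling pathway lists passed the adjusted threshold in the pooled list with peaks assigned to the nearest TSS. In the Dpp pathway 9 of 17 genes had a peak against 3.75 expected (p = 0.0069, adjusted p = 0.055, permutation test): besides shn, the strongest were at Mad, the pathway's transducing Smad gene (signal 186), and the receptor gene wit (142). Replicate 1's own list took the Dpp pathway past the threshold (adjusted permutation p = 0.0032), and replicate 2's did not (adjusted p = 0.15). It also passed with assignment within 5 kb only (9 of 17 genes against 3.19 expected, adjusted permutation p = 0.016), but not with gene bodies (log2 0.79, adjusted p = 0.24), promoter peaks only (log2 1.31, 0.69), the conservative list (log2 1.06, 0.47) or peaks at or above the median signal (log2 1.19, 0.43), against a main log2 of 1.26. Without matching, the Dpp, EGFR and FGF, Wnt and Hox lists all passed (largest adjusted p = 0.012, Fisher's exact test). In the EGFR and FGF list 10 of 20 genes had a peak against 5.41 expected (adjusted permutation p = 0.21), led by the kinase gene Raf, with 4 intronic peaks (strongest signal 312), the EGFR antagonist gene aos (193) and S (148). Among peaks at or above the median signal that list passed, with 9 of 20 genes against 3.26 expected (adjusted permutation p = 0.030). In the Wnt list 9 of 26 genes had one against 5.09 (adjusted permutation p = 0.30), at the kinase gene sgg (194), lin (179), which encodes the Bowl regulator Lines, the feedback inhibitor genes nkd (177) and Notum (133), and lgs (128). The lgs peak was intergenic, 19084 bp from the TSS. In the Notch list the count was 7 of 27 against 3.97 (adjusted permutation p = 0.39), with the corepressor gene gro (183), numb (178), the ubiquitin ligase genes neur (146) and mib1 (114.8), and the coactivator gene mam (113) in front. The Hedgehog list had 4 of 15 against 2.73 (adjusted permutation p = 1), at the receptor gene ptc (139), dally (77.1) and boi (63.8) among others.

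None of the patterning and tissue lists passed the adjusted threshold in the pooled list with peaks assigned to the nearest TSS. Some of the peaks named below lay outside their gene and far from its TSS. The strongest peak lay 18189 bp away for mirr, 17409 bp for abd-A, 15233 bp for mid, 13982 bp for upd1 and 9188 bp for crq. Hox and cofactor genes had a peak in 7 of 13 cases against 3.39 expected (adjusted permutation p = 0.21), led by hth (signal 151, in an intron), abd-A (95.8) and Antp (94.5). Segmentation genes had 7 of 29 against 7.03 (adjusted permutation p = 1), where slp2 (153), mid (98.3) and ftz-f1 had the strongest peaks. Gut genes had 6 of 24 against 5.64 (adjusted permutation p = 1), with drm, lin, dpp (112), the JAK/STAT ligand gene upd1 (87.3) and Stat92E (77.3) in front. The tracheal list had 6 of 19 against 5.36 (adjusted permutation p = 1), with hth, rib (116) and mirr (110), and the appendage list 5 of 20 against 5.78 (adjusted p = 1), with Dll, hth and tio (93.4). The muscle and mesoderm list had 9 of 35 against 7.96 (adjusted permutation p = 1), with promoter peaks at the T-box gene org-1 (223), the heart gene tin (194) and the titin-like gene sls (131). The nervous system list had 8 of 36 against 7.71 (adjusted permutation p = 1), with the pan-neuronal gene elav (298), brat (235) and zfh2 (125). The hemocyte and fat body list had 3 of 20 against 3.19 (adjusted permutation p = 1), at crq (120), ush (114) and the GATA factor gene srp (65.3). The germ line list had 3 of 16 against 2.26 (adjusted permutation p = 1), at bgcn (144), ovo (78.9) and piwi (57.6). Epidermis and cuticle genes had 2 of 29 against 5.14 (adjusted permutation p = 0.39), at grh (94.5), an epidermal transcription factor gene, and ovo. With peaks assigned to gene bodies plus 1 kb upstream, 1 of 29 epidermis and cuticle genes had a peak against 7.16 expected (adjusted permutation p = 0.036). Of the replication-dependent histone genes only 3 had a candidate nearest to them and 0 had a peak, so that list was not tested.

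**Figure D3:**
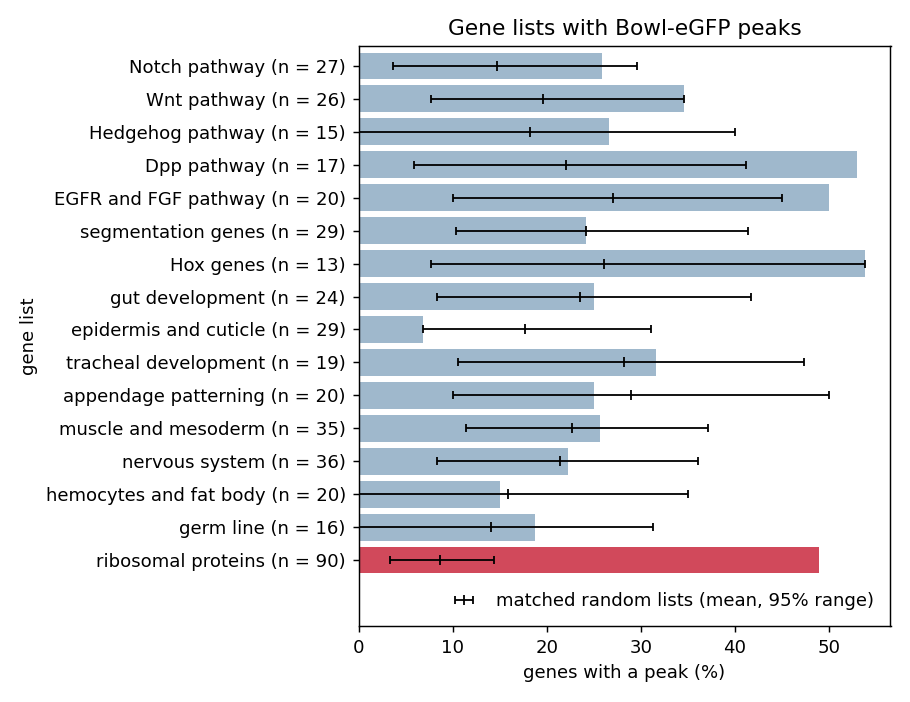
Share of genes with a peak (%, horizontal axis) in each of the 16 tested lists, with the mean and 95% range of matched random lists as black bars. Ribosomal protein genes, with 44 of 90 genes against 7.81 expected, were the list past an adjusted p of 0.05.

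Summits near small RNA genes were few but in excess. Of 2198 summits, 24 lay within 500 bp of a tRNA, snRNA, snoRNA or rRNA gene, 1.09% (0.735 to 1.62) against 0.439% of failing candidates (2.49-fold, p = 1.3e-04, Fisher's exact test). The candidates were not matched on feature class here, so this excess was not separated from the promoter excess of the peaks.

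The word ACAGTAGC, used for the odd-skipped family, was not detectably enriched at summits. It lay within 50 bp of 6 summits, 0.273% (0.125 to 0.594), against 0.19% of matched candidates (1.44-fold, p = 0.49, permutation of matched draws), and ranked 8203 of 32895 words of 8 bases. Its core CAGTAGC lay at 26 summits, 1.18% against 0.708% (1.67-fold, permutation p = 0.017, adjusted p = 0.065 over the panel). Within 100 bp the core's share was 2.41% against 1.46% (adjusted permutation p = 0.0076). Within 50 bp the core passed against flanks 1 kb away (adjusted binomial p = 0.0063). It also passed in replicate 1's list (log2 1.03, adjusted permutation p = 0.013), but not in replicate 2's (log2 0.13, adjusted p = 1), in the conservative list (log2 0.74, adjusted permutation p = 0.22) or among peaks at or above the median signal (log2 0.77, adjusted p = 0.44), where the ratio was much like the main one and the peaks were fewer. A copy of the core lay 21 bp from the summit of the strongest drm peak (2L, 3539535 to 3539541). The other peaks of the odd-skipped family genes had no copy within 200 bp of the summit.

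Among the 19 panel words, 3 passed an adjusted p of 0.05. The CTCF word AGGTGGCGC lay at 9 summits, 0.409% against 0.0743% of matched candidates (5.51-fold, adjusted permutation p = 0.0038), and the GAGA factor word GAGAGAG at 47, 2.14% against 1.25% (1.71-fold, adjusted p = 0.0038). The homeodomain word TAATTA was less frequent at peaks, 7.19% against 8.98% (log2 -0.32, adjusted permutation p = 0.022). The GAGA word was not in excess against flanks 1 kb away (log2 -0.23, adjusted binomial p = 0.40) or in replicate 2's own list (log2 -0.016, adjusted permutation p = 1). The CTCF word missed the threshold in replicate 1's list (log2 2.21, adjusted permutation p = 0.056). The TAATTA deficit turned to a log2 of 0.21 against those flanks (adjusted binomial p = 0.16). It missed the threshold in the lists of replicate 2 (log2 -0.0041, adjusted permutation p = 1) and replicate 1 (adjusted p = 0.13). In the conservative list neither TAATTA (log2 -0.30, adjusted permutation p = 0.086) nor GAGA (log2 0.66, adjusted p = 0.15) passed. None of the 3 words passed among peaks at or above the median signal, where the smallest adjusted permutation p of the 3 was 0.080, though their ratios were no smaller (log2 2.72 for CTCF, 0.87 for GAGA and -0.37 for TAATTA). The Zelda, Grainyhead, Pangolin, Su(H), T-box, forkhead, GATA, Caudal, Twist, DREF, M1BP, Tramtrack, Stat92E and CA-repeat words did not pass at 50 bp against matched candidates in the pooled list. DREF passed against the flanks (log2 1.54, adjusted binomial p = 0.0038), which were not matched on promoter class. Twist passed with missing candidates added back (log2 0.66, adjusted permutation p = 0.0475). Within 100 bp Pangolin (log2 -0.58, adjusted permutation p = 0.010), Tramtrack (log2 -0.67, adjusted p = 0.032) and CA-repeat words (log2 0.31, adjusted permutation p = 0.012) passed.

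The highest-ranked 8-base words were others. Within 50 bp AGAGAGCG ranked first, at 41 summits or 1.87% against 0.387% of matched candidates. Within 100 bp the first 2 words were CACAGTGG and CACTGTGC, each near 124 summits, 5.64% against 1.14% and 1.16%. The 7 bases ACAGTGG, chosen for description after the ranking was seen, lay within 100 bp of 227 summits, 10.3% against 2.77% of matched candidates (3.73-fold), a description without a test because the word was picked from that ranking. The share rose with signal, from 5.82% (4.15 to 8.10) in the weakest 25% of peaks to 15.1% (12.3 to 18.3) in the strongest 25%. Read along ACAGTGG, the summit lay downstream of the word in 351 of 425 occurrences within 200 bp, at a median distance of 85 bp (quartiles 61 and 113). At CenG1A the word lay on the minus strand within AAGAGCAGGTACAGTGGTCACTCTACA (2L, 13835533 to 13835559), 85 bp from the summit.

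**Figure D4:**
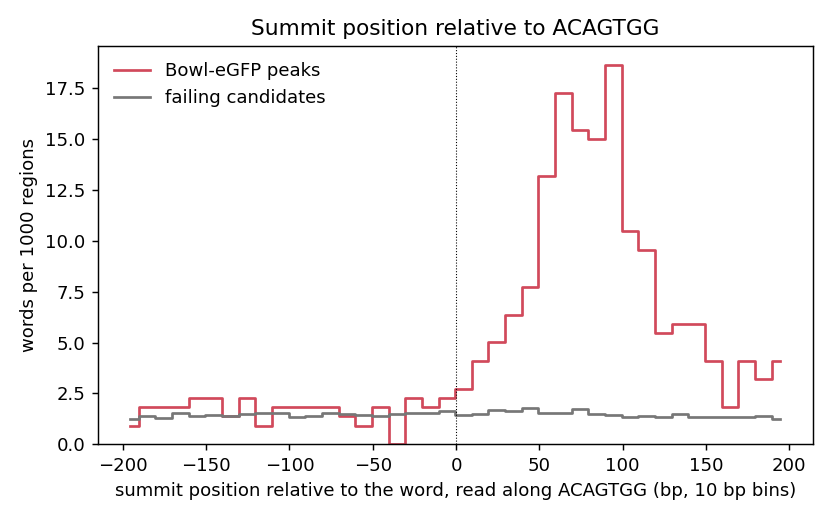
Occurrences of ACAGTGG per 1000 regions (vertical axis) by the position of the summit along the reading direction of the word (bp, bins of 10 bp), in the 2198 Bowl-eGFP peaks and in failing candidates. In peaks the density was highest, 18.7 per 1000, with the summit 90 to 99 bp downstream of the word, and failing candidates stayed near 1.46.

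The replicates differed in how many peaks they yielded. Replicate 1 gave 1662 peaks from 102124 candidates and replicate 2 gave 772 from 106305, a ratio of 2.15, and their covered lengths were 470931 and 190997 bp. Of replicate 2's peaks, 633 or 82.0% (79.1 to 84.5) met a replicate 1 peak, and 38.4% (36.1 to 40.8) of replicate 1's met a replicate 2 peak, where random draws of candidates gave means of 1.78% and 0.749%. Of the pooled peaks, 640 were met in both replicates (median signal 160), 793 in replicate 1 alone (81.5), 120 in replicate 2 alone (82.4) and 645 in neither (64.8). Across 2189 pooled peaks with a signal in both replicates, Spearman's rho was 0.51 (0.48 to 0.54) and Pearson's r of log2 signals was 0.61. This is a description across peaks that had already been selected by IDR. That IDR came from another ranked list than the one that compares the replicates, from which the conservative list was cut. Pearson's r was lower over all 126986 candidates, 0.28, and higher in the conservative list, 0.77. No test between replicates was possible with 1 library each.

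**Figure D5:**
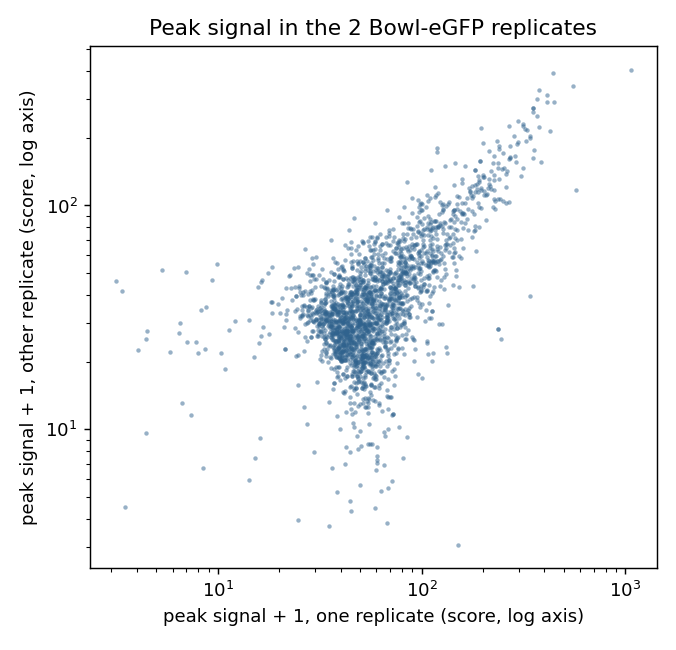
Peak signal plus 1 (score, log axes) of 2189 pooled peaks in one replicate against the other, a point per peak. Spearman's rho was 0.51, over peaks selected by IDR in another ranked list than the one that compares the replicates.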

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

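The tests of signal strength and of neighbouring pairs in this part were chosen after the result was seen.

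Each peak list lacked some candidates that had passed its IDR threshold, a signal in the ranked lists that the main comparisons above did not use. They numbered 89 for the pooled list, 62 for the conservative list, 68 for replicate 1 and 28 for replicate 2. The strongest in the pooled data had a signal of 950.8, rank 2 of all candidates, in an intron of cbt (2L, 480962 to 481233), a Krüppel-like zinc-finger gene. Other genes with a strong missing candidate, named after their values were seen, were Lk6 (signal 549), larp (443) and the trithorax-group gene trx (405), and 6 of the 100 strongest candidates were missing. The arm 3R held 51 of the 89, 57.3%, against 22.2% of listed peaks (p = 2.8e-12, Fisher's exact test), and 2L held 23. The missing candidates lay in clusters, which this test counts as independent, so its p is too small.

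Weaker signal did not account for the gaps, because the median signal of the missing candidates was 82.9, above the lower quartile of listed peaks, 66.6. Removal by position may account for them: among passing candidates, 35 neighbouring pairs within 5 kb were both missing, against at most 6 in 1000 permutations, 80 of the 89 were overlapped by a missing candidate of another list, and 1 of the 89, at CG18428, was overlapped by a listed peak of another list. The criterion written beforehand was no overlap by a listed peak, and it was missed by that 1 candidate. The 80 overlaps are not separate evidence, because the pooled data come from the alignments of both replicates. The reading of removal by position therefore rests on the test of neighbouring pairs. Whether these regions lack the word ACAGTGG cannot be told apart from chance with so few: 6.9% of 87 held it within 100 bp, against 10.3% of listed peaks of like signal (95% range 4.6 to 17.2). A share inside that range had been set beforehand as the result against this explanation, but that criterion was wrong, since the range also reaches shares well under 10.3%. No biological explanation was tested, as the design has 1 group.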

How the results depend on the processing

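No paired analysis was possible because there was 1 group. Of 141 values under alternatives, 105 kept their direction and side of the threshold, or stayed in their range. The rank agreement on the main arms alone is among the 105 and could not change, because the pooled list had 0 peaks elsewhere. Alternatives that added back missing candidates, left out weak peaks, used promoter peaks only or left out ribosomal protein genes were chosen after seeing the data. The promoter excess passed its threshold in every alternative run (log2 1.21 to 2.38), as did ribosomal protein genes (1.93 to 2.79) and small RNA genes (0.93 to 1.43). The share of replicate 2 peaks met in replicate 1 was 71.6% with reciprocal overlap of 50% and 90.9% among peaks at or above each median. Arms or scaffold classes past the threshold, 1 in the pooled list (other scaffolds), numbered 3 among peaks at or above the median signal and 0 to 1 in single replicates. The Bowl word passed, by a p without adjustment over the panel, only as the core CAGTAGC (log2 0.74), and the full word lay at 0 summits of replicate 2's list, so no ratio was given there. Panel words past the threshold, 3 in the pooled list, numbered 7 within 100 bp, 1 in the conservative list, 0 among peaks at or above the median, and 1 to 2 in single replicates. Lists past it, 1 in the pooled list, numbered 2 with assignment within 5 kb, 2 with gene bodies, 5 without matching, 2 among peaks at or above the median, and 1 to 2 in single replicates. Among features, the Bowl word, the 3 called words, and the Dpp and ribosomal protein lists, the log2 values that changed sign were the intron ratio with 200 bp promoters (0.057), GAGA against flanks (-0.23) and in replicate 2 alone (single replicates -0.016 to 1.27, the latter unchanged in sign), TAATTA against flanks (0.21), and 2 that never passed: the full Bowl word in replicate 1 alone (-0.27), and the 5' UTR share with 1000 bp promoters (-0.35), in the conservative list (-0.17), at or above the median signal (-1.54), without weak peaks (-0.080) and in single replicates (-1.57 to -0.50). Smaller lists have less power; otherwise the cause was not tested. Depth is unknown, so the difference in yield between replicates cannot be set against it.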

Other observations

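The word ACAGTGG, the lists of Polycomb and trithorax and of mitochondrial ribosomal protein genes, and their tests were chosen after the peaks were seen, and the comparison of direction with other orderings after the direction of ACAGTGG was seen.

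Genes of the Polycomb and trithorax groups, which maintain silent and active states of developmental genes, carried peaks more often than matched random lists. Of 32 such genes, 14 had a peak against 4.94 expected (2.83-fold, p = 2.2e-04, adjusted p = 4.4e-04 over 2 added lists, permutation test). Besides ph-p, the strongest peaks lay at Psc (signal 549), tara (513), Trl (452), which encodes the GAGA factor, and osa (329). The list was drawn up because ph-p stood among the strongest peaks, so it is not independent evidence. Mitochondrial ribosomal protein genes, prompted by mRpL41, had 5 of 71 genes with a peak against 5.19 expected (adjusted permutation p = 1), unlike the cytoplasmic ones, a difference that was not itself tested.

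The word ACAGTGG lay beside the summits and in a set direction. It occurred 30 times within 25 bp of the 2198 summits and 190 times 51 to 100 bp away, a flank to centre ratio of density of 3.23. A fixed offset from a directional site is a candidate explanation: in 91.1% of the 190 flank occurrences (86.1 to 94.3) the summit lay downstream, in replicate 1's list 87.8%, in replicate 2's 96.2%, and in failing candidates 51.6%. Placing the summit at the middle of the interval did not account for it in the 230 narrower peaks, of which 195 had the summit over 2 bp from the middle. Of the 1968 peaks at or above the median width, 1965 had the summit within 2 bp of the middle. Distances to the summit in those are in effect distances to the middle of the interval, and this check does not cover them. The ratio in the 230 was 14.3 (5.48 to 63.2). It rested on 56 flank and 2 centre occurrences, and a floor on the centre count set the upper limit, so its size is uncertain. Base composition stays open for the dip at the centre, where 7.16% of 419 other orderings of the 7 bases had as high a ratio. That share has no minimum count, any ordering absent from the centre counts as reaching the ratio, and some orderings overlap the word itself. Base composition does not stay open for the direction. There each ordering was counted in its own commoner direction, upstream or downstream, as the 91.1% of ACAGTGG is its commoner direction. The highest such share was 86.1% and the median 56.5% among the 124 orderings with at least 20 flank occurrences. Whether the word is particular to Bowl-eGFP was not tested, as no other factor was analysed here.

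ACAGTGG on both sides was seen in 25 peaks, 1.14% against 0.181% expected if the sides were independent (odds ratio 10.9, p = 7.1e-15, Fisher's exact test). The word was picked from these peaks, and its share rose with signal. A mix of peaks rich and poor in the word also gives such an excess, so it does not show paired sites. Of the 20 leading 8-base words within 100 bp, several of which overlap ACAGTGG, 17 had a set direction (adjusted p under 0.05, exact binomial tests). Each word was written on the strand for which the summit lay downstream more often. That the words share a downstream summit therefore carries no information, and only the size of each share does. GAGAGAAA had the summit downstream in 56 of 71 flank occurrences (adjusted exact p = 2.3e-06), GGGCGTAG in 19 of 19 (adjusted p = 6.9e-06, exact binomial test), and AGAGAGCG in 30 of 58 (adjusted p = 0.90). Summits themselves were rich in A and T, with a GC content of 37.2% within 10 bp against 43.2% at 90 to 110 bp.

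Most of the ribosomal protein peaks did not lie near small RNA genes, since 5 of 47, 10.6% (4.63 to 22.6), lay within 500 bp of one. For those 5 a small RNA gene stays a possible source. Among all 2198 summits 1.09% lay as near. Signal at strongly transcribed promoters without a sequence word is another possible explanation, which the counts of ACAGTGG cannot decide. That word was picked from these peaks and lay within 100 bp of only 10.3% of all of them, so lacking it does not mean lacking any word. It lay within 100 bp of 1 of 43 ribosomal protein promoter peaks, 2.33%, against 8.21% of other promoter peaks of like signal (p = 0.23, permutation). With so few peaks that difference cannot be told apart from chance either. Of the 47 peaks, 70.2% were met in replicate 1 and 42.6% in replicate 2, against 65.1% and 34.4% of other peaks. No biological explanation was tested, as the design has 1 group.

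Of the listed peaks, 68 had a signal under the median of failing candidates, and 67 of these lay within 300 bp of a stronger listed or missing peak, a description without a test because peaks of low signal have mostly stronger neighbours.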
